A study of Mus musculus with 8 samples.

How the data were processed

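The series measured messenger RNA of whole dissected tracheae from mouse embryos at embryonic day 11.5 (E11.5) and E13.5. Per the labels, total RNA was extracted with Trizol and sequencing libraries were made with the Nextera XT kit, which fragments and tags complementary DNA by transposition and does not mark the strand of origin. The genotype labels are control and WlsShhCre. There were 8 libraries in 4 groups of 2, control and mutant at each stage, and every library was placed in its group by the stage and genotype in its labels. The labels do not say whether the 2 replicates of a group were separate embryos, pools or litters, and they give no sequencing batch.

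The authors deposited 2 tables, 1 per stage, with 37528 gene entries at E11.5 and 37532 at E13.5. Each table held, per the file headers, a raw count and a read density for every library. The deposited raw counts are estimated counts, since between 76.3% and 82.6% of the values above 0 in a library were not whole numbers. The submitters' processing notes name the mouse genome build mm9 and the tools Bowtie2 2.1.0, TopHat2 2.0.8, Cufflinks 2.0.2 and DESeq; which of them counted the reads, with which gene annotation, is not given in the sources used here. The deposited read density was found from the values to be an RPKM, that is the count per kilobase of gene model, scaled to the total of its own column. The gene model lengths implied by count and density differed between the 2 tables for 1034 of the 17561 genes in which they could be compared. The stages were therefore counted against gene models that were not the same, and the stage differences can include that. The RPKM values served only for this check, and all tests used the counts. A few entries name no gene, 2 in the E11.5 table and 6 in the E13.5 table; they held 0.000985% to 0.0253% of a library's counts and were left out of library sizes and tests. Counts were summed over the 483 entries of 239 gene symbols that had more than 1, which left 37282 symbols, and were rounded to whole numbers. The 13 protein genes of the mitochondrial genome had a summed count of 0 in all libraries, so the share of mitochondrial transcripts could not serve as a measure of RNA quality.

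Total counts per library ranged from 9.9 to 18.48 M, and both E13.5 mutant libraries were deeper than the 6 others. The reads carry no molecular identifiers, so intervals and floors given for low counts cover counting error only. A gene without any count in both libraries of a group was given a floor of 3 counts over the group, and its fold change is then a lower bound. With 1 to 3 counts the ratio is given with its 95% Poisson interval. CPM, counts scaled to a common library size, were computed with library sizes scaled by the trimmed mean of M-values (TMM), whose factors lay between 0.980 and 1.020.

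Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 14901, and a quasi-likelihood model with 1 mean per group was fitted robustly to all 8 libraries together, with 4 residual degrees of freedom. From this fit came the genotype effect at E11.5, the genotype effect at E13.5, the difference of these effects (the stage by genotype interaction), and the stage effect in controls and in mutants. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and adjusted p in the text means this value unless camera is named. A gene was called when its adjusted p was under 0.05. The common biological coefficient of variation was 7.8%. Replicates differed by more than sampling noise in every group, with chi-square per degree of freedom from 3.45 to 8.63, so no library was treated as a copy of another; Pearson correlations of log2 CPM between replicates were 0.990 to 0.992. The design had assumed whole counts; rounding the estimated counts was the only change the unit required.

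A set of 27 gene lists was written before the data were examined, from textbook knowledge of the tissue. They cover Wnt/beta-catenin targets, Wnt ligands, Wnt receptors and secreted modulators, cartilage, smooth muscle, mesenchymal patterning of the foregut, and hedgehog, BMP, FGF-ERK and Notch signalling. For cell types and states they cover airway epithelium, basal and differentiated epithelium, distal lung, endothelium, erythroid, immune, neuronal and glial, skeletal muscle, cardiac muscle, thyroid with parathyroid and thymus, mesothelium and pericytes, fibrous connective tissue, cell cycle, growth arrest and apoptosis, hypoxia and glycolysis, immediate early and heat shock, and sex-linked genes. Each list was compared with all other genes by limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the 27 lists within a comparison. Camera was repeated with the correlation estimated from the data, and fry tested whether a list's genes moved on balance in 1 direction. No list call of any comparison held with the estimated correlation. That estimate was -0.018 for Wnt/beta-catenin targets and 0.009 for BMP response, both under the preset value, and 0.764 for skeletal muscle. A list call lost in this way is therefore not by itself a sign that the list's members were correlated. Member calls are given adjusted over all genes and adjusted over the list alone.

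The rule for the genes named in the text was also fixed before the data were examined. Wls and Shh are always named. Per comparison these are joined by the called genes with a mean log2 CPM of at least 1, both libraries of 1 group above both of the other, and the largest changes, up to 10 per direction for the genotype comparisons and 6 for the interaction and stage. Members of the fixed lists may be named as well. Predicted genes and sex-linked genes were not named under this rule; Xist, Ddx3y, Anpep and Enpep were singled out after their values were seen. Because the largest decreases at E13.5 turned out to be genes of adult intestine, and the largest stage changes genes listed at 0 in all of 1 table, the same rule was applied again after the data were seen. It was applied to genes with at least 1 CPM in both E13.5 mutant libraries and to genes with the same implied length in both tables.

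The steps were tested on simulated counts with 200 genes per comparison changed by known amounts, at the real depth, over 14684 genes. Genes were drawn independently, each with the same fitted spread in all groups. Real control replicates differed more at E13.5 than at E11.5 (chi-square per degree of freedom 7.51 and 3.45), which the simulation does not reproduce. At E11.5 the fit recovered 40.3% of simulated log2 changes of 0.5, 82.1% of those of 1 and 95.5% of those of 2; at E13.5 it recovered 55.2%, 80.6% and 98.5%. None of the recovered genes had the wrong direction. False calls made up 9.4% of the simulated calls at E11.5 and 12.4% at E13.5, above the nominal 5%, so calls with an adjusted p near 0.05 are less certain than that value states.

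The alternatives fixed beforehand were RLE and upper quartile scaling or none, no low-count filter or a stricter one (at least 5 CPM in 2 libraries), DESeq2 1.42.0, limma-voom and the replicate number as a block. Further ones were a fit that was not robust, a fit on the 4 libraries compared, each library left out in turn, and a 2-fold minimum. Those added later were leaving out genes under 1 CPM in both E13.5 mutants, thinning the deeper libraries, offsets for GC content and gene length, and keeping genes of equal implied length. Groups of 2 libraries allow neither a test for a library that stands apart within its group nor a count over other splits of the samples. No genome coordinates are given, because the reference used here for GC content is of another build than mm9.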

Results

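RNA was sequenced from whole tracheae of mouse embryos at E11.5 and E13.5, from controls and from embryos with the genotype WlsShhCre, called mutants here. Wls encodes the cargo receptor that Wnt ligands need to leave the cell, and Cre driven from the Shh locus acts in the epithelium that lines the trachea and not in the surrounding mesenchyme. The comparison asks what deletion of Wls does to gene expression in the tracheal tissue at each stage. Each of the 4 groups held 2 libraries. Total estimated counts were 10.96 and 11.9 M in the E11.5 controls, 9.9 and 11.43 M in the E11.5 mutants, 10.58 and 10.62 M in the E13.5 controls, and 18.48 and 16.76 M in the E13.5 mutants. Nothing in the labels says that replicates were separate animals. Xist, a transcript of female cells, stood at 6.34 and 1220 CPM in the E13.5 mutants, so these 2 replicates came from different embryos. In the controls the replicate with less Xist had more of the Y-linked Ddx3y. These were 1170 and 1850 against 43.2 and 32.8 CPM at E11.5, and 2670 and 1840 against 19.8 and 48.2 CPM at E13.5, so control replicates differed in their share of male and female cells. The E11.5 mutants had 846 and 526 CPM of Xist and 52.2 and 61.8 CPM of Ddx3y. Apart from E13.5 mutant replicate 1 each library thus held transcripts of both sexes, as pooled embryos would give. At both stages each mutant library had less Xist and more Ddx3y than each control library. The share of male cells therefore went with genotype, and the genotype effects at both stages can include it.

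Transcript levels of the targeted gene went with the genotype labels in all 8 libraries. Wls stood at 155 and 164 CPM in the E11.5 controls against 118 and 109 CPM in the mutants, and at 168 and 158 CPM in the E13.5 controls against 73.9 and 71.7 CPM in the mutants. The log2 fold change was -0.49 at E11.5 (SE 0.06, adjusted p = 0.003) and -1.16 at E13.5 (SE 0.06, adjusted p = 1.5e-07). The loss was larger at the later stage (interaction -0.67, SE 0.09, adjusted p = 8.5e-04). The transcript that remained can include that of cells in which this Cre does not act, which values of whole tracheae cannot separate. Shh itself, whose locus carries Cre, gave log2 values of -0.16 at E11.5 (adjusted p = 0.963) and 0.42 at E13.5 (adjusted p = 0.230); the E11.5 value turned to 0.17 without mutant replicate 1, and the E13.5 value passed on the 4 libraries of that stage (adjusted p = 0.0254).

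**Figure D1:**
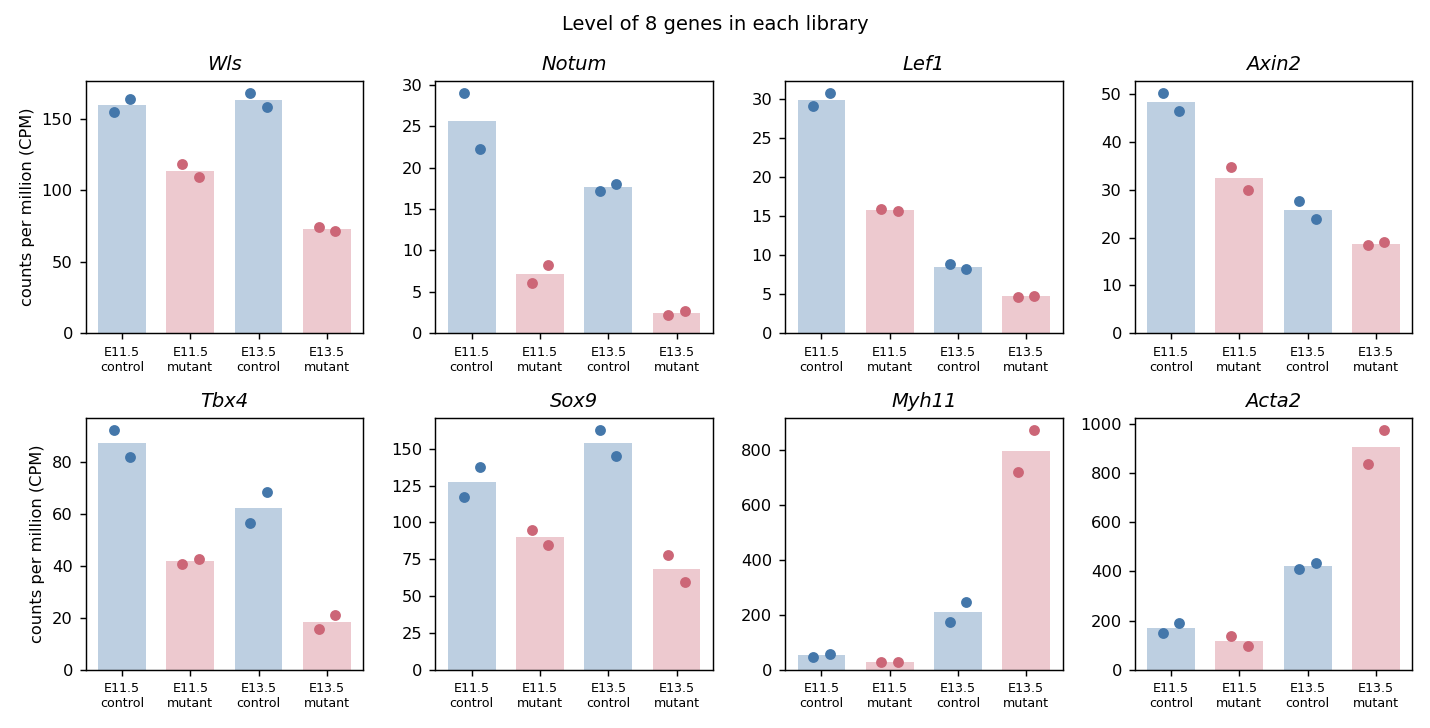
CPM of 8 genes, 1 panel each; points are single libraries, bars the mean of the 2 libraries of a group, blue control and red mutant. Wls, Notum, Lef1 and Tbx4 lay lower in both mutant libraries at each stage, while Myh11 averaged 797 CPM in the E13.5 mutants against 209.6 CPM in their controls.

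At E11.5, 5 of 23 Wnt/beta-catenin targets and 5 of 30 mesenchymal patterning genes were lower in the mutant tracheae, and the patterning list as a whole did not differ from other genes. Notum, a secreted enzyme that inactivates Wnt ligands and is itself induced by Wnt signalling, averaged 25.6 ± 4.81 CPM (SD, n = 2) in controls and 7.10 ± 1.55 CPM in mutants. Its log2 fold change was -1.84 (SE 0.18, adjusted p = 3.6e-04). The T-box genes Tbx4 and Tbx5, which act in lung and tracheal mesenchyme, fell by 1.06 and 0.97, and the homeobox gene Msx1 fell by 1.83. Dcx, which encodes a microtubule protein of young neurons, rose by 0.97 (SE 0.13, adjusted p = 0.006). Several of these calls were lost with 1 library left out. For control replicate 1 and mutant replicates 1 and 2 the adjusted p was 0.13, 0.24 and 0.167 for Tbx4, and 0.134, 0.056 and 0.0761 for Msx1. Dcx had 0.0993 and 0.0832 without control replicates 1 and 2.

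Among the Wnt/beta-catenin targets at E11.5, 5 of 23 tested genes fell, 0 rose and 18 did not pass. The 5 were Notum, Lef1 (-0.92, adjusted p = 0.00283), Tcf7 (-0.81), Nkd1 (-0.76) and Axin2 (-0.58, adjusted p = 0.0204), and 7 fell when adjusted over the list alone. Notum and Lef1 passed whichever library was left out. Without control replicate 1 and mutant replicates 1 and 2 the adjusted p was 0.247, 0.133 and 0.0946 for Tcf7, and 0.13, 0.132 and 0.126 for Nkd1. Axin2 had 0.259 and 0.072 without control replicates 1 and 2, and 0.156 without mutant replicate 2. The list as a whole was lower than other genes (camera adjusted p = 3.49e-05, but adjusted p = 0.211 with an estimated correlation). Of the 9 Wnt ligands 0 passed in edgeR and 1 was higher adjusted over the list alone. An unadjusted p under 0.05 was found for 1, and DESeq2 and limma-voom called 0. The ligand list had a median of 0.20 and camera adjusted p = 0.0191, which became adjusted p = 0.336 with an estimated correlation. It was 0.105 and 0.185 without control replicate 2 and mutant replicate 2. The mesenchymal patterning list had 5 of 30 members lower, namely Tbx2 (-0.58, SE 0.06), Tbx3 (-1.02, SE 0.11), Tbx5, and with the losses given above Tbx4 and Msx1, with 8 lower and 1 higher adjusted over the list alone. As a list it did not differ from other genes (camera adjusted p = 0.0944). Msx1 was also the 1 BMP response gene of 18 that fell (5 adjusted over the list alone; camera adjusted p = 0.00179, adjusted p = 0.336 with an estimated correlation), and Bmp4 stood at -0.44 (adjusted p = 0.123, but 0.048 on the 4 libraries of this stage).

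Genes of both mesenchymal tissues that form the tracheal wall tended to lie lower at E11.5. In the cartilage list 2 of 25 fell, Sox5 (-0.66, adjusted p = 0.00457) and Sox6 (-0.75, adjusted p = 0.0318), also 2 adjusted over the list alone. Sox5 had an adjusted p of 0.0565 without control replicate 2 and 0.053 without mutant replicate 1. For Sox6 it was 0.114 and 0.217 without control replicates 1 and 2, and 0.218 and 0.223 without mutant replicates 1 and 2. Of the list's members 21 lay below 0, with a median of -0.60 (camera adjusted p = 2.42e-06, adjusted p = 0.463 with an estimated correlation). Sox9, the transcription factor that starts cartilage formation, stood at -0.50 (SE 0.15, adjusted p = 0.425) and the cartilage collagen Col2a1 at -0.37 (SE 0.30, adjusted p = 0.919). On the 4 libraries of this stage both passed (0.0107 and 0.0406), and Sox9 also with DESeq2 (0.012). In the smooth muscle list Cnn1 alone fell (-0.91, adjusted p = 0.0119), 2 adjusted over the list alone. Its adjusted p was 0.084 and 0.105 without control replicates 1 and 2, and 0.0876 and 0.125 without mutant replicates 1 and 2. Of the list's 28 members 25 lay below 0, with a median of -0.28 (camera adjusted p = 3.26e-06, adjusted p = 0.336 with an estimated correlation). Acta2 at -0.55, Myh11 at -0.93 and Myocd at -0.57 did not pass, although Myh11 did with DESeq2 (0.0142), with the replicate block (0.00133) and on the 4 libraries of this stage (7.28e-04). Of 25 fibrous connective tissue genes Thbs2 fell (-0.49, adjusted p = 0.0204), 2 adjusted over the list alone, and its adjusted p was 0.224, 0.0719, 0.056 and 0.14 without each library in the same order. That list had camera adjusted p = 0.00339, adjusted p = 0.538 with an estimated correlation, and 0.177 and 0.502 without control replicate 1 and mutant replicate 2.

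Markers of other cell types also differed between the E11.5 libraries as lists, although edgeR called 0 of their members. The 25 neuronal and glial genes had a median of 0.64, and 8 were higher adjusted over the list alone. An unadjusted p under 0.05 was found for 12, with 1 called by DESeq2 and 0 by limma-voom (camera adjusted p = 1.19e-07, adjusted p = 0.336 with an estimated correlation). All 16 erythroid genes lay below 0 with a median of -0.75. An unadjusted p under 0.05 was found for 6, with 0 adjusted over the list alone and 0 by DESeq2 or limma-voom (camera adjusted p = 1.70e-06, adjusted p = 0.377 with an estimated correlation). Of 18 immune genes 17 lay above 0, with a median of 0.40. In that list 7 had an unadjusted p under 0.05, with 1 adjusted over the list alone and 0 by DESeq2 or limma-voom (camera adjusted p = 1.85e-06, adjusted p = 0.336 with an estimated correlation). The 29 epithelial genes had a median of 0.14, with 12 at an unadjusted p under 0.05, 6 higher adjusted over the list alone and 0 by DESeq2 or limma-voom. Their camera adjusted p = 5.03e-04 became adjusted p = 0.538 with an estimated correlation, and 0.436 and 0.475 without control replicate 2 and mutant replicate 2. Skeletal muscle genes had a median of 0.73 with 0 of 23 at an unadjusted p under 0.05 or called by edgeR, DESeq2 or limma-voom (camera adjusted p = 8.86e-05, adjusted p = 0.538 with an estimated correlation, 0.112 without mutant replicate 2). Of 20 immediate early and heat shock genes, which respond to handling of tissue, 18 lay below 0 with a median of -0.34. None had an unadjusted p under 0.05 or was called by edgeR, DESeq2 or limma-voom. Camera gave adjusted p = 0.00179 for them, adjusted p = 0.538 with an estimated correlation and 0.177 without control replicate 1, in which Fos stood at 53.4 CPM against 6.11 to 7.98 CPM in the 3 others. Cardiac genes had a median of -0.62, with 2 of 16 at an unadjusted p under 0.05, 1 lower adjusted over the list alone and 0 by DESeq2 or limma-voom. Their camera adjusted p = 0.0465 became adjusted p = 0.693 with an estimated correlation, 0.436 without control replicate 2, and 0.259 and 0.0706 without mutant replicates 1 and 2. Hypoxia and glycolysis genes had a median of -0.08, with 1 of 18 at an unadjusted p under 0.05 and 0 by DESeq2, limma-voom or adjusted over the list alone. For these camera gave adjusted p = 0.0457, adjusted p = 0.63 with an estimated correlation, and 0.295 and 0.814 without control replicate 1 and mutant replicate 1. Of the 5 sex-linked genes 4 lay above 0 with a median of 0.59, but edgeR, DESeq2 and limma-voom called 0 and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.0885).

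Further genes with large changes at E11.5 rose or fell as follows. Hlf (0.93), Ntn1 (0.81), Iqgap2 (0.77), Apoe (0.68), Dbc1 (0.59), Pawr (0.55), Celf2 (0.45) and Kctd12 (0.33) were higher, where Ntn1 encodes the secreted guidance cue netrin-1 and Apoe a lipid carrier. Among the decreases, below Notum and Msx1, came the relaxin receptor gene Rxfp1 (-1.50), the skeletal transcription factor Runx2 (-1.50), the neuropeptide gene Gal (-1.48), Alx4 (-1.31), Kcnk3 (-1.16) and the matrix protein gene Smoc2 (-1.07, SE 0.07, adjusted p = 9.0e-06). In all, 54 of 14901 genes passed, 11 higher and 43 lower, of which 15 changed at least 2-fold, and 1123 had an unadjusted p under 0.05 where chance alone gives 745. Without control replicate 1 the count was 20, and without mutant replicate 2 it was 69 with 49 of them higher. It was 92 with no low-count filter, 90 with DESeq2, 29 with limma-voom and 120 on the 4 libraries of this stage. Besides Wls, 32 of the genes named for this comparison passed, and 9 of them did so whichever library was left out, among them Notum, Rxfp1, Smoc2, Lef1, Tbx2, Tbx3, Tbx5 and Tpbg.

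At E13.5, 7 of 25 cartilage and 13 of 18 BMP response genes were lower in the mutant tracheae, and 13 of 28 smooth muscle and 20 of 29 epithelial genes were higher. With an estimated correlation none of these 4 lists passed as a whole (adjusted p = 0.479, 0.126, 0.455 and 0.455). Sox9 averaged 154 CPM in controls and 68.7 CPM in mutants (-1.16, SE 0.15, adjusted p = 0.0039). The smooth muscle myosin gene Myh11 averaged 210 ± 49.6 CPM (SD, n = 2) in controls and 797 ± 108 CPM in mutants (1.93, SE 0.21, adjusted p = 0.00672, but 0.0691 when the 4 libraries of this stage were fitted alone). Notum fell from 17.6 to 2.42 CPM (-2.86, SE 0.20, adjusted p = 1.1e-06). The E13.5 mutant libraries also stood apart from the 6 others in another way, since many genes of adult intestine, present in those 6, were at or near 0 in both. The summed level of 53 intestine markers was 69.3 and 82.5 CPM against 182.2 and 174.6 CPM in the E13.5 controls. Of the 48 markers with at least 18 counts over the 6 libraries, 11 had 0 counts in both mutants, while 11 averaged at least 1 CPM there, Anpep (18.6 CPM) and Enpep (16.2 CPM) the most.

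The cartilage list had 7 of 25 members lower, 0 higher and 18 not past the test, and 12 lower adjusted over the list alone (median -0.74, camera adjusted p = 1.16e-06, adjusted p = 0.479 with an estimated correlation). Besides Sox9 these were its partners Sox5 (-0.54) and Sox6 (-0.48), the matrix genes Hapln1 (-0.83) and Matn4 (-1.81), the sulfation enzyme gene Papss2 (-0.95) and Wwp2 (-1.45), a ubiquitin ligase gene that hosts a cartilage microRNA. Col2a1 at -0.74 (SE 0.29, adjusted p = 0.242) and Acan at -1.41 (SE 0.65, adjusted p = 0.269) did not pass, but Col2a1 did with limma-voom (0.0321) and a fit that was not robust (0.04). Without control replicate 1 the adjusted p was 0.0752 for Sox6, 0.0725 for Hapln1, 0.13 for Matn4, 0.115 for Papss2 and 0.0686 for Wwp2. Without control replicate 2 it was 0.14 for Sox6, 0.106 for Matn4, 0.122 for Papss2 and 0.0567 for Wwp2. Without mutant replicate 2 it was 0.0867 for Sox6 and 0.0923 for Papss2. In the same libraries the skeletal muscle list had a median of 1.50 and the cardiac muscle list one of -1.45.

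The smooth muscle list had 13 of 28 members higher and 0 lower, with 18 higher and 3 lower adjusted over the list alone. Its median was 0.49 (camera adjusted p = 4.64e-07, adjusted p = 0.455 with an estimated correlation, fry adjusted p = 0.0189). Myocd, the coactivator that switches on contractile genes, rose by 1.71 (SE 0.16, adjusted p = 6.04e-04), Tpm2 by 0.93, Lmod1 by 1.43, Ppp1r12b by 0.78 and Cnn1 by 0.50. Cnn1 lost its call on the 4 libraries of this stage (adjusted p = 0.0694). Acta2 lost its call with the replicate block (adjusted p = 0.122) and with no low-count filter (0.0548). Acta2 rose by 1.10 (SE 0.20, adjusted p = 0.0352), and its adjusted p was 0.179 and 0.138 without control replicates 1 and 2, and 0.091 and 0.112 without mutant replicates 1 and 2. Epithelial markers rose in the same libraries by a median of 0.69, endothelial markers had a median of -0.46, and the intestine markers were lower as given above.

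Of the 18 BMP response genes 13 fell and 0 rose, also 13 adjusted over the list alone (median -0.60, camera adjusted p = 1.92e-07, adjusted p = 0.126 with an estimated correlation, fry adjusted p = 0.0023). They included the immediate BMP targets Id1 (-0.83), Id2 (-0.46) and Id3 (-0.82), the signal transducer Smad9 (-0.63), Msx1 (-1.13), Msx2 (-2.77) and the ligand Bmp4 (-0.87, SE 0.10, adjusted p = 8.58e-05). Hey1 (-0.56) is among them and is also a Notch target. Msx1 and Hey1 lost their calls without some library, with an adjusted p of up to 0.13 and 0.113. Several of these genes are expressed in endothelium too, and 6 of 20 endothelial genes fell in these libraries, 11 adjusted over the list alone. Among them were the receptor genes Tie1 (-0.72), Tek (-0.78) and Eng (-0.48), and the list's median was -0.46 (camera adjusted p = 6.25e-06, adjusted p = 0.479 with an estimated correlation).

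The Wnt/beta-catenin targets were divided at E13.5. Of 23 genes 9 fell and 5 rose, the same numbers adjusted over the list alone, and 9 did not pass. Camera gave adjusted p = 0.237, while fry found a decrease on balance (adjusted p = 0.0214). Tcf7 (-1.15), Lef1 (-0.86), Axin2 (-0.46), Nkd1 (-0.39) and the cell cycle gene Ccnd1 (-0.80) fell with Notum, whereas Sp5 (1.43), Lgr5 (1.11), Tnfrsf19 (1.02), Rnf43 (0.78) and Kremen1 (0.65) rose. Sp5 lost its call without any 1 of the 4 libraries (adjusted p = 0.0763 to 0.171), and Nkd1 without control replicate 2 and mutant replicates 1 and 2 (0.317, 0.143 and 0.129). Axin2 lost it without control replicate 1 and mutant replicate 1 (0.148 and 0.057), and Tnfrsf19 without control replicates 1 and 2 (0.0816 and 0.0621). Cdx1 is a member too and is an intestinal transcription factor; it had 30 counts in the controls and 0 in the mutants, at least 16.7-fold lower. Among 9 Wnt ligands Wnt2 (1.40), Wnt4 (1.23) and Wnt7b (0.89) rose, Wnt5a (-0.51) and Wnt5b (-0.41) fell, and 4 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.186). Wnt4 and Wnt7b are epithelial genes and stand in the epithelial list, which rose as a group. Of 26 Wnt receptors and modulators 5 fell, Rspo4 (-3.91), Ror1 (-1.05), Rspo3 (-0.64), Dkk3 (-0.63) and Fzd1 (-0.53), and Sfrp1 rose (0.59), with 7 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.422). Wnt5b, Ror1, Rspo3, Dkk3 and Sfrp1 also lost their calls without some library, with an adjusted p of up to 0.322, 0.0871, 0.215, 0.289 and 0.1.

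Mesenchymal patterning genes were divided, with 10 of 30 lower and 8 higher, 11 and 10 adjusted over the list alone (camera adjusted p = 0.422). Tbx2 (-1.39), Tbx3 (-1.43), Tbx4 (-1.75), Tbx5 (-1.37), Hoxa5 (-1.39) and the joint ligand gene Gdf5 (-1.64) fell. Foxf2 (2.60, SE 0.13, adjusted p = 1.46e-07), its relative Foxf1a (1.05), Nkx6-1 (1.60) and Eya1 (1.38) rose. Foxf1a had an adjusted p of 0.11 and 0.0656 without control replicates 1 and 2. Foxf genes and Nkx6-1 are known from gut and tracheal mesenchyme that forms muscle. These libraries also had less of the intestine markers and of endothelial genes, as above.

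Of 29 epithelial genes 20 rose, 0 fell, and 25 rose adjusted over the list alone. All 29 lay above 0, with a median of 0.69 (camera adjusted p = 2.96e-16, adjusted p = 0.455 with an estimated correlation, fry adjusted p = 0.0191). Examples are Epcam (0.69), Cdh1 (0.51), Spint2 (0.74), Esrp2 (0.84), Foxa2 (0.83), Sox2 (0.90) and, with the smallest rise of the 20, Nkx2-1 (0.38). In the basal and differentiated epithelial list 5 of 15 rose, 1 fell and 9 did not pass, 6 and 1 adjusted over the list alone. Krt5, a keratin of basal cells, rose by 4.11 (SE 0.57, adjusted p = 0.006) and Krt15 by 3.43 (SE 0.47, adjusted p = 0.018). Ccno (0.97) and Insm1 (1.09) also rose, while Trp63, the transcription factor of basal cells, stood at 0.47 (adjusted p = 0.101). Krt17, outside the genes picked by size, rose by 2.02 (adjusted p = 0.011). The member that fell, Reg3g (-5.51), is abundant in intestine. Camera gave adjusted p = 0.00828 for this list, adjusted p = 0.479 with an estimated correlation and 0.0627 without control replicate 2. Without control replicates 1 and 2 the adjusted p was 0.0539 and 0.0647 for Krt5, 0.135 and 0.121 for Krt15, and 0.0668 and 0.1 for Krt17. Nkx2-1, Cdh1 and Insm1 also lost their calls without some library, with an adjusted p of up to 0.114, 0.0525 and 0.0762. With the 4 libraries of the stage alone the adjusted p was 0.112 for Krt5 and 0.145 for Krt15.

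**Figure D2:**
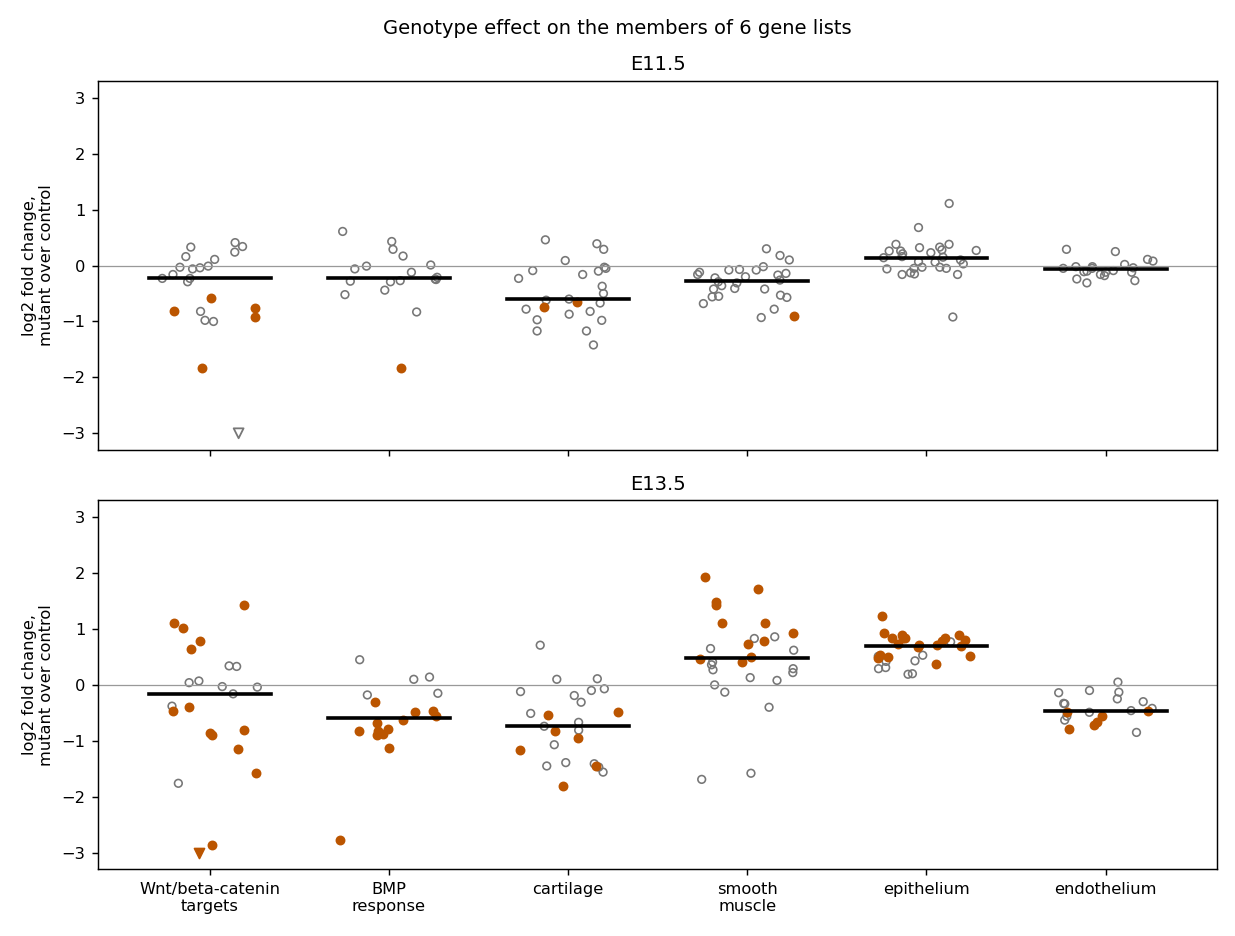
Log2 fold changes, mutant over control, of the tested members of 6 gene lists at E11.5 (top) and E13.5 (bottom), where filled points passed an adjusted p of 0.05, open points did not, lines are medians and triangles stand for values under -3. At E13.5 all 29 epithelial genes lay above 0, and the medians were 0.49 for smooth muscle, -0.74 for cartilage and -0.60 for BMP response.

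Other signalling lists gave few calls. FGF-ERK response genes had 4 of 16 higher, the feedback inhibitors Spry1 (0.89), Spry2 (0.67) and Spry4 (1.27) with Shisa2 (0.50), and Myc lower (-0.83), 5 and 2 adjusted over the list alone. The list had camera adjusted p = 0.0205, adjusted p = 0.479 with an estimated correlation and 0.204 without mutant replicate 1. Of 13 hedgehog genes the target Ptch1 rose (0.48) and the coreceptor genes Boc (-0.58) and Cdon (-0.42) and Gli3 (-0.27) fell, 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.89). Of 16 Notch genes Dll4 (0.59) and Lfng (0.69) rose and Hey1 and Hey2 (-0.95) fell, the same numbers adjusted over the list alone (camera adjusted p = 0.894). Fibrous connective tissue genes had 2 of 25 higher and 7 lower, among them Tnmd (1.84), Thbs2 (-0.52) and Col3a1 (-0.31), with 3 and 9 adjusted over the list alone (camera adjusted p = 0.0682). Of 33 cell cycle genes edgeR called 0, DESeq2 0 and limma-voom 0, also 0 adjusted over the list alone, and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.463). Of 15 growth arrest and apoptosis genes Cdkn1a rose (0.90) with 1 other and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.906). Of 18 hypoxia and glycolysis genes Egln3 rose (1.06), also 1 adjusted over the list alone (camera adjusted p = 0.237). Immediate early and heat shock genes had a median of 0.40 with 0 of 20 called by edgeR, 0 adjusted over the list alone, 2 each by DESeq2 and limma-voom and 4 at an unadjusted p under 0.05. For these genes camera gave adjusted p = 0.0152, adjusted p = 0.614 with an estimated correlation, and 0.32 and 0.254 without control replicate 1 and mutant replicate 1. Of the genes named here, Shisa2, Gli3, Dll4, Hey1, Hey2, Col3a1, Tnmd and Cdkn1a lost their calls without some library, with an adjusted p of up to 0.343 for Dll4.

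Markers of tissues around the trachea and of blood also differed between the E13.5 groups, with few members past the test and no list past it with an estimated correlation. Thyroid genes were lower in the E13.5 mutants, with 3 of 9 in the thyroid, parathyroid and thymus list past the test and 3 adjusted over the list alone. The median was -1.43 (camera adjusted p = 2.07e-05, adjusted p = 0.229 with an estimated correlation). The 3 were Pax8 (-4.61, SE 0.59, between -3.73 and -6.79 without mutant replicates 1 and 2, and adjusted p = 0.0543 with DESeq2), thyroglobulin, Tg (-2.13), and Iyd, with 48 counts in controls and 2 in mutants, a ratio of 40.1 (95% interval 10.5 to 341). Skeletal muscle genes had a median of 1.50 with 2 of 23 higher, Tnni2 (2.04) and Tnnc2 (2.19), and 3 adjusted over the list alone (camera adjusted p = 2.07e-05, adjusted p = 0.538 with an estimated correlation). Without control replicates 1 and 2 the adjusted p was 0.178 and 0.19 for Tnni2, and 0.254 and 0.217 for Tnnc2. Without mutant replicate 1 Tnni2 was 1.03 (adjusted p = 0.218). Cardiac genes had a median of -1.45 with 2 of 16 lower, Nppa (-3.76) and Nkx2-5 (-1.43), also 2 adjusted over the list alone (camera adjusted p = 3.24e-05, adjusted p = 0.479 with an estimated correlation). Nkx2-5 was -0.85 (adjusted p = 0.312) without control replicate 1 and -1.14 (adjusted p = 0.135) without mutant replicate 2. Erythroid genes had 3 of 16 lower, among them Epb4.2 (-1.61) and Rhag, the latter with 15 counts against 2 (ratio 12.5, 95% interval 2.92 to 113). Adjusted over the list alone 3 passed (camera adjusted p = 0.00132, adjusted p = 0.479 with an estimated correlation). Immune genes had 2 of 18 lower, Lyz2 (-0.70) and Pf4 (-1.49), and 3 adjusted over the list alone (camera adjusted p = 0.0111, adjusted p = 0.484 with an estimated correlation and 0.204 without mutant replicate 1). Pf4 was -0.79 (adjusted p = 0.368) without control replicate 1 and -1.10 (adjusted p = 0.164) without mutant replicate 1. Lyz2 had an adjusted p of 0.0693 and 0.258 without control replicates 1 and 2, and 0.0873 and 0.126 without mutant replicates 1 and 2. Neuronal and glial genes had 4 of 25 higher and 1 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.653). Ret (0.76), Foxd3 (0.70) and Erbb3 (0.55) of neural crest cells rose and Dbh (-0.84) of noradrenergic neurons fell. Mesothelial and pericyte genes had 2 of 13 higher and 2 lower, among them Kcnj8 (1.49) and Pdgfrb (-0.72), with 2 and 3 adjusted over the list alone (camera adjusted p = 0.422). Of 8 distal lung genes Cldn18 (1.40) and Nkx2-1 rose and 2 fell, among them Ctsh (-0.97), with 3 and 2 adjusted over the list alone (camera adjusted p = 0.754). Of 5 sex-linked genes edgeR called 0, DESeq2 1 and limma-voom 4, also 0 adjusted over the list alone, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.0552). Their median was 1.29 with 4 above 0, and the Y-linked Ddx3y stood at 106 and 66.8 CPM in the mutants against 19.8 and 48.2 CPM in the controls. At E11.5 it was 52.2 and 61.8 against 43.2 and 32.8 CPM, so both mutants lay above both controls at each stage. Of the other genes named here, Rhag, Epb4.2, Dbh, Foxd3, Ret, Pdgfrb, Ctsh, Cldn18 and Nkx2-1 lost their calls without some library, with an adjusted p of up to 0.257 for Epb4.2.

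By the size rule, the largest rises at E13.5 were Gdnf (4.23, SE 0.34, adjusted p = 4.0e-06), a growth factor for enteric neurons, and, with the losses given for them above, Krt5 and Krt15. They were followed by the claudin gene Cldn10 (3.06), Nppc (2.99), Cer1 (2.85), Itih2 (2.67), the muscarinic receptor gene Chrm2 (2.65), Trim29 (2.65) and the retinoic acid synthesis gene Aldh1a1 (2.64, SE 0.13, adjusted p = 7.3e-08). The largest decreases were all genes of adult intestine with 0 counts in both mutant libraries. Reg3b, an antimicrobial lectin, was at least 207-fold lower, Dmbt1 at least 174-fold, and Sprr2a1 at least 51.8-fold. The Paneth cell defensin genes Defa24, Defa20, Defa17, Defa22, Defa3, Defa21 and Defa-rs7 were lower by at least 51.3-fold to 181-fold. They are near-identical copies among which reads may be split. Defa24, the 181-fold end of that range, lost its call without any 1 of the 4 libraries (adjusted p = 0.0851 to 0.123). Among genes with at least 1 CPM in both mutants, the largest decreases after Notum were Prlr (-2.48), Lgi3 (-2.46), Gsg1l (-2.37), Iigp1 (-2.27), Smpx (-2.19), Vsnl1 (-2.10), Kcnj5 (-2.09), Gata5 (-2.08) and Ano4 (-2.06). Kcnj5 was -1.09 without control replicate 1 (adjusted p = 0.0744), and its adjusted p was 0.165 and 0.201 without mutant replicates 1 and 2. For Vsnl1 it was 0.107 and 0.0752 without mutant replicates 1 and 2, and for Iigp1 0.103 and 0.0942 without control replicates 1 and 2. In all, 1755 of 14901 genes passed, 889 higher and 866 lower, 543 of them at least 2-fold; with the 637 genes under 1 CPM in both mutants left out the count was 1602, and without control replicate 1 it was 934. Besides Wls, 138 of the genes named for this comparison passed, and 87 of them did so whichever library was left out, 84 under every alternative.

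**Figure D3:**
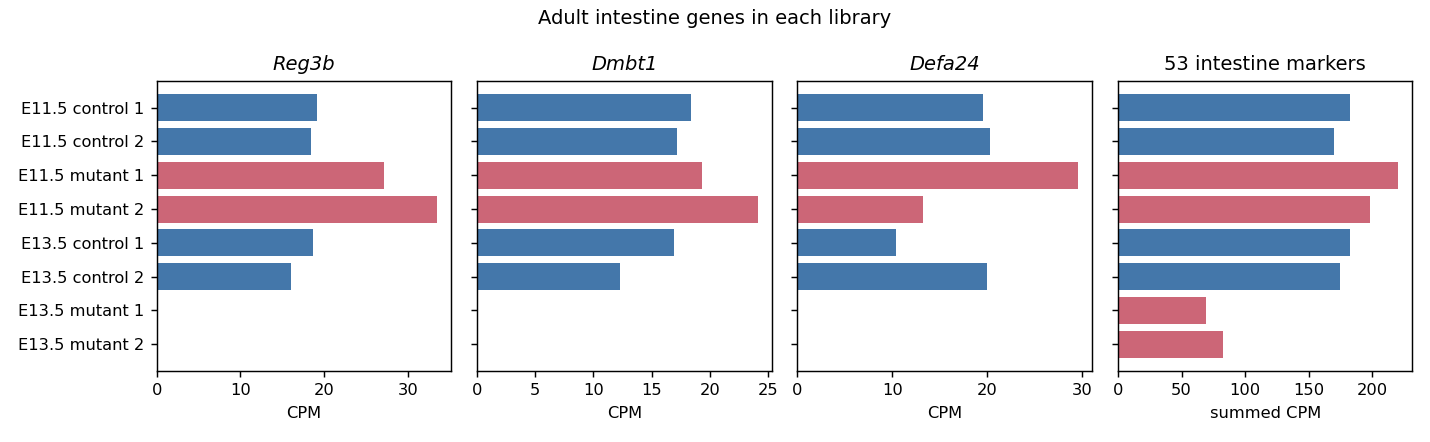
Level of 3 intestinal genes and summed level of 53 intestine marker genes, in CPM, in each library; blue bars are controls and red bars mutants. The summed level lay between 169.5 and 220.5 CPM in 6 libraries and at 69.3 and 82.5 CPM in both E13.5 mutant libraries, in which Reg3b, Dmbt1 and Defa24 had 0 counts.

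The genes that fell at E11.5 mostly fell at E13.5 as well, although the stages share no library. Of the 43 genes lower at E11.5, 33 were also lower at E13.5, where 2.5 would be shared by independent lists (1-sided Fisher's exact test over genes, p = 1.02e-32). Of the 11 higher genes 4 were shared, among them Celf2, Iqgap2 and Ntn1, against 0.7 (p = 0.00296, same exact test). Cnn1, Smoc2 and Tpbg were lower at E11.5 and higher at E13.5, but Cnn1 did not pass at E11.5 with any 1 of its 4 libraries left out. Without E13.5 control replicate 1 the E13.5 adjusted p was 0.0727 for Cnn1 and 0.0521 for Tpbg. Of the 54 genes, 46 (85.2%) kept their sign. Over all 14901 genes the fold changes of both stages were nearly unrelated (Pearson 0.014, Spearman 0.084), and over the 10894 genes with a mean log2 CPM of at least 3 Pearson was 0.185; genes are not independent replicates.

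The genotype effect itself differed between the stages for 497 genes, 243 with a more positive and 254 with a more negative effect at E13.5. Of the smooth muscle list 11 of 28 genes had a more positive effect at E13.5 and 0 a more negative one, 15 adjusted over the list alone. Of the epithelial list 10 of 29 had a more positive effect and 0 a more negative one, 19 adjusted over the list alone (camera adjusted p = 1.72e-10, adjusted p = 0.649 with an estimated correlation). The smooth muscle list had camera adjusted p = 1.55e-11, adjusted p = 0.232 with an estimated correlation and fry adjusted p = 0.018. Myh11 moved from -0.93 at E11.5 to 1.93 at E13.5 (difference 2.86, SE 0.33, adjusted p = 0.021, but 0.126 and 0.112 without E11.5 mutant replicates 1 and 2). Cnn1 moved from -0.91 to 0.50 (difference 1.41, adjusted p = 8.30e-04) and Smoc2 from -1.07 to 0.75 (difference 1.83, adjusted p = 2.03e-07). Among BMP response genes 3 of 18 had a more negative effect at E13.5, Id1 (-0.62), Id3 (-0.70) and Msx2 (-1.93), and 9 adjusted over the list alone (camera adjusted p = 5.15e-05, adjusted p = 0.184 with an estimated correlation). For the 25 cartilage genes edgeR called 0 differences, 3 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0 (camera adjusted p = 0.0907). Notum (-1.02, adjusted p = 0.0626), Sox9 (-0.66, adjusted p = 0.203) and Tbx4 (-0.69, adjusted p = 0.12) did not pass this test. Notum did with no low-count filter (0.0309), Sox9 with DESeq2 and the replicate block (0.00732 and 0.0273), and Tbx4 with the same (0.0354 and 0.0081). By the size rule the largest positive differences were Gdnf (3.33), Col19a1 (2.92), Myh11, Aldh1a1 (2.71), Tll1 (2.44) and Foxf2 (2.44). The largest negative ones were the intestinal genes Reg3b, Dmbt1, Defa20, Defa17, Sis and Defa3. Among genes with at least 1 CPM in both E13.5 mutants they were Syt4 (-2.96), Prlr (-2.69), Glis3 (-2.37), Nrgn (-2.34), Pcdh20 (-2.28) and Ano4 (-2.23). Col19a1 lost its call without 7 of the 8 libraries (adjusted p = 0.0528 to 0.158) and kept it without E13.5 mutant replicate 2. Nrgn lost it without 6 (adjusted p = 0.0675 to 0.177) and kept it without E11.5 mutant replicate 2 or E13.5 control replicate 2. Without E11.5 control replicate 2 and E11.5 mutant replicate 1 the adjusted p of Prlr was 0.0615 and 0.111, and that of Pcdh20 was 0.0505 without E11.5 control replicate 1. Of the 70 genes named for this comparison that passed, Wls included, 39 did so whichever library was left out. The count of calls was 279 without E11.5 control replicate 1, 320 without E11.5 mutant replicate 1 and 287 without E13.5 control replicate 1.

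From E11.5 to E13.5 the control trachea gained transcripts of cartilage, muscle, connective tissue and epithelium and lost those of dividing and primitive blood cells. Cartilage genes rose in 15 of 25 cases and fell in 1, 16 and 1 adjusted over the list alone (median 1.40, camera adjusted p = 5.06e-06, adjusted p = 0.445 with an estimated correlation). Smooth muscle genes rose in 16 of 28 cases and fell in 2, also 16 and 2 adjusted over the list alone (camera adjusted p = 2.04e-04, adjusted p = 0.445 with an estimated correlation). Epithelial genes rose in 24 of 29 cases, 24 adjusted over the list alone (median 0.82, camera adjusted p = 5.01e-09, adjusted p = 0.445 with an estimated correlation). Connective tissue genes rose in 20 of 25, 21 adjusted over the list alone (camera adjusted p = 8.21e-09, adjusted p = 0.445 with an estimated correlation). Cell cycle genes fell in 31 of 33 cases, 32 adjusted over the list alone (median -0.44, camera adjusted p = 4.11e-11, adjusted p = 0.445 with an estimated correlation). Erythroid genes fell in 13 of 16, 13 adjusted over the list alone (median -2.60, camera adjusted p = 1.43e-06, adjusted p = 0.445 with an estimated correlation), with the embryonic globin genes Hbb-bh1 at -5.59 and Hba-x at -3.99. Markers of neighbouring or entering tissue rose in the same libraries. They were 11 of 16 cardiac genes (median 3.89, camera adjusted p = 8.77e-04, adjusted p = 0.672 with an estimated correlation) and 6 of 23 skeletal muscle genes (median 2.06, camera adjusted p = 1.98e-04, adjusted p = 0.672 with an estimated correlation). The others were 16 of 25 neuronal and glial genes (median 1.30, camera adjusted p = 6.43e-04, adjusted p = 0.489 with an estimated correlation) and 12 of 18 immune genes (median 1.04, camera adjusted p = 1.02e-04, adjusted p = 0.445 with an estimated correlation). Adjusted over each list alone 12, 1, 17 and 13 rose, and 1 cardiac and 2 neuronal or glial genes fell. Wls did not differ between the stages in controls (0.03, SE 0.06, adjusted p = 0.728).

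In the mutants smooth muscle genes rose in 26 of 28 cases, 27 adjusted over the list alone (median 1.64, camera adjusted p = 2.29e-10, adjusted p = 0.442 with an estimated correlation). All 29 epithelial genes rose, 29 adjusted over the list alone (median 1.29, camera adjusted p = 1.19e-12, adjusted p = 0.551 with an estimated correlation). Other lists moved in the mutants too, each with an adjusted p of 0.442 or more with an estimated correlation. Cartilage genes rose in 15 of 25 cases, connective tissue genes in 20 of 25 and skeletal muscle genes in 18 of 23, with 17, 21 and 19 adjusted over the list alone (camera adjusted p = 0.00116, 3.52e-08 and 1.45e-05), and 1 cartilage and 1 connective tissue gene fell. Immediate early and heat shock genes rose in 12 of 20 cases, against 2 of 20 in controls (median 1.03, 13 adjusted over the list alone, camera adjusted p = 4.79e-04). Endothelial genes fell in 16 of 20 cases, cell cycle genes in 30 of 33 and erythroid genes in 12 of 16, with 16, 31 and 12 adjusted over the list alone (camera adjusted p = 3.44e-04, 8.84e-11 and 9.29e-06). Shh rose by 0.92 (SE 0.20, adjusted p = 0.005) and Wls fell by 0.64 (adjusted p = 3.5e-06). In all 6320 genes passed between the stages in controls and 7221 in mutants. The genes that the size rule picks here are mostly listed at 0 in all libraries of 1 table, such as Thoc4, Vipar, Pnmal2, Tmem93, Rnf123 and Stard9 at E11.5 and Ccdc72, Ppm1f, Slc25a11, Rrp8, Obfc2b and D1Ertd448e at E13.5. The gene model lengths implied by the tables differ for 1034 of 17561 genes. With equal gene models, the controls' largest rises were heart and muscle genes, Cox6a2, Myh6 (6.25), Myom2, Sln and Csrp3 (5.38), and Tnn. Without E11.5 control replicates 1 and 2 the adjusted p was 0.0641 and 0.0846 for Cox6a2, 0.132 and 0.129 for Myh6, 0.0847 and 0.0749 for Myom2, and 0.107 and 0.104 for Csrp3. Without E13.5 control replicate 1 it was 0.0873 for Myh6 and 0.0664 for Myom2, and 0.0593 for Myom2 without replicate 2. Among their largest falls were those of Hbb-bh1, Hemgn (-4.86), Lin28a (-4.17), Hand1 (-4.16) and Hba-x. The mutants' largest rises were Tnfaip8l3, Aspn, Tnn, Abca8a (6.54), Clec3b and Muc5ac, most of them from few counts at E11.5. Aspn had 3 counts there (ratio 198, 95% interval 67.7 to 964) and Muc5ac 2 (ratio 86, 95% interval 23.6 to 713). The adjusted p without E11.5 mutant replicates 1 and 2 was 0.0576 and 0.0802 for Aspn and 0.0662 and 0.0996 for Clec3b, and for Muc5ac it was 0.0553 without replicate 2. Stage and deposited table, and with it any sequencing batch, cannot be told apart in these comparisons, and with genes of equal implied length the counts were 5707 and 6554.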

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

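The results in this part were picked because the test of the stage by genotype interaction found the genotype effect to differ between E11.5 and E13.5. The test of the library split by sign agreement, the comparison of the intestine list with the gene lists, and all tests of the epithelial genes given under the other observations, were chosen after the result was seen. In all, 497 genes differed, and of the 70 named genes among them 39 did so whichever library was left out. For the 31 others the adjusted p without some library was up to 0.247, that of Gdf5. Among those named in this part they are Prlr, Iqgap2, Dbc1, Runx2, Itih2, Myh11, Tpm2, Lmod1, Msx2, Gdf5, Eya1, Id1, Rnf43, Kremen1, Tnfrsf19, Wnt2, Wnt5a, Wnt7b, Rspo3, Epcam, Spint2, Esrp2, Ptch1, Spry1, Shisa2, Cldn18, Tg and Lyz2. Values below are the log2 fold change at E13.5 minus that at E11.5 unless stated otherwise.

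Wls was lower by more at E13.5 (-0.67). Of the genes named for their change at E11.5, Dcx (-1.12), Apoe (-0.95) and Dbc1 (-0.60) had a more negative effect at E13.5, and Ntn1 (1.20), Iqgap2 (0.67), Runx2 (1.47), Smoc2 (1.83) and Tpbg (1.28) a more positive one. Of those named at E13.5, Gdnf (3.33), Itih2 (2.16) and Aldh1a1 (2.71) were more positive, and Prlr (-2.69), Lgi3 (-1.45), Gsg1l (-1.83), Gata5 (-2.05) and Ano4 (-2.23) more negative.

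Smooth muscle genes with a more positive effect were Myh11 (2.86), Cnn1 (1.41), Myocd (2.27), Tpm2 (0.75), Ppp1r12b (0.94) and Lmod1 (1.51), and the list had camera adjusted p = 1.55e-11, but adjusted p = 0.232 with an estimated correlation. In the patterning list Tbx2 (-0.81), Msx2 (-1.93), Hoxa5 (-1.25) and Gdf5 (-1.21) were more negative, and Foxf2 (2.44), Nkx6-1 (1.85) and Eya1 (1.09) more positive. BMP response was lower as a list (camera adjusted p = 5.15e-05, adjusted p = 0.184 with an estimated correlation), with Id1 (-0.62) and Id3 (-0.70). Id1 had an adjusted p of 0.0674 without E11.5 control replicate 2 and 0.0553 without E13.5 control replicate 1.

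Among Wnt genes Rnf43 (0.67), Kremen1 (0.66), Tnfrsf19 (2.00), Wnt2 (1.13) and Wnt7b (0.79) were more positive, and Ccnd1 (-0.64), Wnt5a (-0.49), Fzd1 (-0.50) and Rspo3 (-1.28) more negative. Epithelial genes were higher as a list (camera adjusted p = 1.72e-10, adjusted p = 0.649 with an estimated correlation), with Epcam (0.48), Spint2 (0.48) and Esrp2 (0.68). Without E11.5 control replicate 1 the adjusted p was 0.118, 0.0574 and 0.0649 for these 3, and without E13.5 control replicate 1 it was 0.102 for Epcam and 0.0525 for Esrp2. For Epcam it was also 0.0909 and 0.0521 without E11.5 mutant replicates 1 and 2. Ptch1 (0.45), Spry1 (0.64), Shisa2 (0.82), Egln3 (0.86) and Cldn18 (1.44) were more positive, and Myc (-0.76), Tg (-2.51) and Lyz2 (-1.23) more negative.

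Other lists had these camera adjusted p: FGF-ERK response higher 0.0497, basal and differentiated epithelium higher 0.0438, hypoxia and glycolysis higher 0.0205, and immediate early and heat shock higher 9.77e-05. For lists that were lower it was 0.00141 for endothelium, 3.53e-06 for immune, 0.00409 for neuronal and glial, 0.0139 for cardiac muscle, and 7.57e-06 for thyroid, parathyroid and thymus genes. With an estimated correlation the adjusted p of these 9 lists was 0.66 for FGF-ERK response, basal and differentiated epithelium, immediate early and heat shock, endothelium, and neuronal and glial genes. It was 0.797 for hypoxia and glycolysis, 0.504 for immune, 0.842 for cardiac muscle and 0.184 for thyroid, parathyroid and thymus genes.

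The intestinal genes Reg3b and Dmbt1 were not lower in the E11.5 mutants (30.3 against 18.8 CPM in controls, and 21.7 against 17.8 CPM). Many intestinal genes had a more negative effect at E13.5, with Reg3g at -6.22. For those at 0 in both E13.5 mutant libraries the adjusted p of the difference was 6.52e-08 for Reg3b, 1.07e-06 for Dmbt1, 3.23e-05 for Defa20, 0.00261 for Defa17, 1.60e-04 for Defa22, 0.0026 for Defa3, 8.68e-05 for Defa21, 6.05e-05 for Sprr2a1, 0.00175 for Defa-rs7 and 0.00601 for Cdx1.

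A first explanation of the intestinal genes is that reads of an adult intestine library entered the 6 other libraries and not both E13.5 mutant libraries. The summed level of the intestine list differed by a ratio of only 1.30 between the highest and the lowest of those 6 libraries. Its members also kept their order between E11.5 and E13.5 controls, with Spearman 0.92 over 48 genes and 0.88 over the 37 under 1 CPM in the E13.5 mutants. An admixture needs both values. They do not settle it, since 8 of the 27 gene lists of the tissue varied less over the same libraries and 23 had a Spearman of at least 0.8, so expression in the tissue could look the same. Not all members were missing either, as 11 averaged at least 1 CPM in the E13.5 mutants. Lower intestinal expression caused by the deletion cannot be told from this, since the median of the list at E11.5 was 0.22. That these genes respond to the deletion at the later stage therefore remains at most a hypothesis.

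The E13.5 genotype effect goes with that split of the libraries, so technical causes of the split might account for it. Depth does not, since the number of calls was 96.3% of the full one when the mutants were thinned to the depth of their controls. GC content and gene length do not account for the number of calls, since offsets for both gave 109.7% of it on the same genes. With the offsets 1082 genes were higher and 856 lower, against 889 and 866 in the main fit. Of these 1938 calls with offsets 1624 were shared with the main fit, so a bias in single calls was not excluded. The split as the whole cause is not borne out, because 85.2% of the E11.5 calls had the same sign at E13.5 although the E11.5 libraries do not show it. That rests on the 43 lower genes, of which 90.7% kept their sign, against 63.6% of the 11 higher ones. Over the 1769 genes called at either stage it was 63.5% and over all genes 52.3%, so for most E13.5 calls a part of the split in the effect stays open. A batch difference that adds to the genotype effect was not excluded, and an effect of the deletion stays a hypothesis.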

How the results depend on the processing

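Groups of 2 libraries limit every comparison, and leaving a library out leaves a group with a lone sample, which is then assumed to vary like the other groups. At E11.5, 54 genes passed. The count was 92 with no low-count filter, 90 with DESeq2, 29 with limma-voom, 120 on the 4 libraries of that stage and 15 with a 2-fold minimum. It ranged from 20 (without control replicate 1) to 69 (without mutant replicate 2). At E13.5, 1755 passed, 934 to 1641 with a library left out and 543 with a 2-fold minimum. For the interaction 497 passed, 279 to 675 with a library left out and 237 with a 2-fold minimum, and 1648 of the 6320 stage calls in controls kept a 2-fold minimum. A 2-fold minimum lowers counts by its construction; for the others the cause was not tested.

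Shh at E11.5 ranged from -0.62 to 0.17 with a library left out, and Wls between the stages in controls from -0.02 to 0.07, where it was -0.02 without replicate 1 of either control group. Neither passed in the first place, and the cause was not tested. The Pearson correlation of both genotype effects was 0.014 over all genes and 0.185 at a mean log2 CPM of at least 3. With an estimated correlation 0 gene lists passed at E11.5, 0 at E13.5, 0 for the interaction and 0 for stage in controls and in mutants, against 14, 13 and 12 with the preset value for the first 3. Fry gave 0, 5 and 3.

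Replicate numbers do not pair these samples by the labels, and the deviations of equal numbers correlated by 0.07 at E11.5 and 0.06 at E13.5 over 10894 genes. With the replicate number as a block the count was 90 at E11.5, 1827 at E13.5, 561 for the interaction, and 4420 and 5363 for stage in controls and mutants.

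Of the other counts at E13.5, scaling gave 1753 to 1787, no filter 1906, the stricter filter 1560, DESeq2 1231, limma-voom 1744, a fit that was not robust 1715, the 4 libraries alone 1523 and thinning 1690. Over the named values, called or not, leaving a library out left the outcome unchanged in 1207 cases. A call was lost in 336 and added in 10, and the direction turned in 3, those of Shh and Wls above. DESeq2 left 286 unchanged and lost 21 calls, limma-voom left 269 unchanged and lost 41, and RLE scaling changed none of 312. Unchanged outcomes include values that were not called in either fit. Wls passed under every alternative at both stages, from -0.43 to -0.54 at E11.5 and from -1.11 to -1.20 at E13.5. Simulated log2 changes of 0.5 were recovered in 40.3% of cases at E11.5, so small changes are missed at this depth and group size.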

Other observations

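All tests of the epithelial pattern in this part were chosen after the result was seen. At E11.5 the secretory cell genes Scgb3a2 and Cyp2f2 had 33 and 4, and 23 and 4, counts in the 2 control libraries and 0 in both mutant libraries. They were at least 11.6-fold and 8.46-fold lower by counting error only, with most counts in control replicate 1. At E13.5 the mutants lay on either side of the controls for Scgb3a2, with 2.85 and 8.54 against 4.96 and 4.78 CPM. Cyp2f2 was higher in both mutants, with 3.17 and 27 against 0.936 and 0.75 CPM. The keratin genes that rose at E13.5 stood at 10.9 and 26.8 CPM against 1.4 and 0.75 CPM in controls for Krt5, 60 and 124 against 9.17 and 7.87 CPM for Krt15, and 9.83 and 18.49 against 4.03 and 2.91 CPM for Krt17.

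The E13.5 libraries differed in several genes outside the lists of the tracheal wall, and not only between replicates. For Myog, Myh6, Pax8 and Egr1 both mutants lay on the same side of both controls, so these genes also differed with genotype. Xist stood at 6.34 CPM in E13.5 mutant replicate 1 and at 526 CPM or more in all other libraries. Myog was 66.3 and 28.7 CPM in the mutants and 13.2 and 15.9 CPM in the controls, Myh6 127 and 20.2 against 526 and 218 CPM, and Pax8 0.0537 and 0.527 against 5.9 and 8.34 CPM. The immediate early gene Fos was 148 and 39.1 CPM in the mutants and 4.59 and 71 CPM in the controls, and Egr1 275 and 105 against 31 and 92 CPM.

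All 29 epithelial genes lay higher in the E13.5 mutants. If a lower share of mesenchyme had raised every other cell type, endothelial genes would rise too. The epithelial median exceeded the endothelial one by 1.16, so a lower share of mesenchyme alone does not account for the pattern. A lower share of mesenchyme joined by less endothelium could leave the same gap and was not tested. A larger share of epithelium in the dissected mutant tissue stays possible. The 29 values had an interquartile range of 0.34, which met a bound set after they were seen, and ran from 0.19 to 1.23. That spread was not compared with the spread of other lists, so it does not show that the genes moved by 1 common factor. A common factor of the size of the epithelial median falls short of the measured rises of Krt5 and Krt15. These exceeded the median by at least 2.73 and, under every alternative, by at least 2.13, where the highest epithelial value was 1.23. Both genes were picked for the size of their rise, which favours such an excess, so a larger share of epithelium is not excluded for them. Their calls were lost without control replicates 1 and 2, where the values were 4.63 and 3.73 for Krt5 and 3.54 and 3.32 for Krt15. They were also lost when the 4 libraries of the stage were fitted alone (adjusted p = 0.112 and 0.145), with values of 4.11 and 3.43 as before. For Krt17 the excess was 1.33, which became 0.81 without mutant replicate 2, so for it the share stays open as well. What raised these keratins, picked because they rose, was not tested.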
